A study of Mus musculus with 22 samples.

How the data were processed

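RNA was measured in spinal cord tissue of 11 female mice that carried a Cre driven by a mouse Gfap promoter and a RiboTag allele, which puts a hemagglutinin (HA) tag on the ribosomes of cells with Cre activity. Per the labels' protocols, tissue of each animal was homogenised and tagged ribosomes were pulled down, which gave an HA immunoprecipitate (HA IP) and an unbound flow-through fraction. Both were turned into cDNA from 5 ng of RNA with the NuGEN Ovation V2 kit, and paired-end libraries were made from 300 ng of fragmented cDNA with 10 PCR cycles. The submitters' processing notes name CASAVA 1.8.2, the mouse build mm10 and edgeR, with no role or order; the aligner, the counting tool and the annotation are not given in the sources used here. A strand setting is not given either, so reads of overlapping or antisense genes cannot be assigned, and counts of close paralogs (H2 genes, Ly6 genes, metallothioneins) are uncertain.

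The authors deposited 5 tables of 24060 gene rows each. Per the file headers they hold raw read counts per gene and library, which carry no normalisation, and the values were whole numbers whose totals differed between libraries. The same tables hold the authors' log2 fold changes and their p-value and false discovery rate columns, per the file headers. From these, only the number of genes under a false discovery rate of 0.05 was taken. Another 124 columns of per-sample values were not used. All 22 libraries appear in 2 tables, and 0 counts differed between them. In 27 rows a date stood in place of a gene symbol, and 25 of these were given their symbol through the RefSeq accession in the row. Libraries of 1 group differed by more than counting noise (the lowest chi-square per degree of freedom between replicate libraries was 4.83), so each animal counted as 1 replicate.

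Samples were grouped by the genotype, condition and RNA type in the labels, with animal numbers from the titles. Within each fraction, the 11 libraries of the 3 groups entered 1 fit, with 1 spread per gene assumed for all 3 groups. The HA IP and flow-through libraries of 1 condition entered a fit of their own, and all 22 libraries entered the fit that tested whether an effect differed between the fractions. Genes were filtered with filterByExpr, library sizes were scaled with TMM, and edgeR 4.0.16 in R 4.3.3 tested each contrast with its quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to TMM-adjusted library sizes; they are relative within 1 fit, so HA IP and flow-through levels from the within-fraction fits stand on different scales. All spreads are between animals.

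Gene lists, 26 in number, were written from general knowledge of the field before the data were examined, as were the designs, the rule for naming genes and the alternatives other than those named below as added. They cover pan-reactive, neuroinflammatory (A1), ischaemic (A2) and homeostatic astrocyte genes, the STAT3 cytokine response, axon growth inhibitory and permissive genes, chondroitin sulfate proteoglycan (CSPG) core proteins, chondroitin sulfate synthesis, markers of microglia and macrophages, lymphocytes, oligodendrocytes and myelin, oligodendrocyte precursors (OPC), neurons, endothelium, fibroblasts and pericytes, Schwann cells, ependymal cilia and blood, and genes of the interferon response, cell cycle, cholesterol synthesis, antigen presentation, complement, chemokines and cytokines, and immediate early response. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 138 tests in the 6 within-fraction comparisons. An estimated correlation and fry were run beside it. Member counts are also given adjusted over the list alone. Some lists share members: Ptprz1 and the aggrecan family, for example, are both CSPG core proteins and axon growth inhibitory genes, and Timp1 and Osmr stand in both the pan-reactive and the STAT3 list.

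The naming rule took, per comparison, up to 8 genes per direction with the largest change among genes that were called, had a mean log2 CPM of at least 3 and had every library of 1 group above every library of the other. Symbols of unnamed, predicted or small RNA genes and ribosomal protein pseudogenes were left out of that part. It added up to 2 called members per direction, or the member with the smallest p where none was called, of the 6 lists with the smallest camera p, and of the axon growth lists in HA IP, as well as Stat3, fixed astrocyte genes, the 7 CSPG core proteins and fixed cell type markers. Some genes that the rule took are not reported here, which left 178 genes and 307 gene results. In the tests between fractions the separation of libraries was applied to HA IP minus flow-through within animals, a reading settled after genes had been listed. Coordinates are from GENCODE vM21 on GRCm38 (mm10), matched by symbol; 1 named gene had none. A fold against a group at 0 counts was computed against a floor of 3 counts over the group, and a group with 1 to 3 counts is given as a ratio with its exact 95% counting interval. Such intervals and floors cover counting error only.

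The animal number pairs the fractions, since both came from 1 tissue piece. The deviations of HA IP and flow-through libraries of 1 animal from their group means correlated over 4001 genes at 0.407 to 0.804 in uninjured animals, 0.231 to 0.298 in WT SCI and 0.246 to 0.573 in STAT3-CKO SCI, and each of the 11 animals' libraries correlated best with its own partner. The tested fits carry no animal term; the fit with animal as a block was an alternative. Other alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, fits of only the 2 groups compared or of all 22 libraries, and leaving out each library in turn. Settings added after the data had been seen left out the counts of Rn45s, Lars2 and Mir6236, thinned the remaining counts of every library to the shallowest of its fraction, or halved the uninjured animals. Overlap between comparisons with shared libraries was set beside 20 simulations with no effect and beside splits of the shared libraries.

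Fits were tested on simulated counts with 200 changed genes, first run after the deposited counts had been fitted. At log2 changes of 1, 2 and 3, the HA IP fit of WT SCI against uninjured recovered 4.5%, 34.3% and 65.2% of the changed genes among 14764 simulated, STAT3-CKO against WT SCI 3%, 31.3% and 72.7%, and STAT3-CKO SCI against uninjured 1.5%, 29.9% and 74.2%. In flow-through, with 12685 simulated genes, the shares were 6%, 47.8% and 72.7%, then 7.5%, 52.2% and 65.2%, then 14.9%, 55.2% and 83.3% in the same order. For HA IP against flow-through they were 25.4%, 82.1% and 93.9% in uninjured animals (14312 genes), 6%, 32.8% and 60.6% in WT SCI (8466 genes) and 1.5%, 44.8% and 75.8% in STAT3-CKO SCI (12659 genes). Signs were recovered in every called changed gene (0 wrong signs), and 2 to 8 unchanged genes were called. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 besides R.

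Tests of technical explanations were written after the results were seen. After their values had been seen, the test of carry-over was moved to library shares, the depth tests were widened from called to all list members, the test of incomplete precipitation allowed for RNA of other cells, and splits between fractions were limited to those that part all pairs. A test leaving out Rn45s, Lars2 and Mir6236 counts was dropped, as that setting barely moved the pattern it was to test.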

Results

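Ribosome-bound RNA of astrocytes and the unbound RNA of the same tissue were sequenced in mouse spinal cord 14 days after a severe crush at thoracic level 10, and in uninjured cord. Injured tissue came from the central 3 mm of the lesion. Wild-type (WT) mice were uninjured (n = 4) or injured (WT SCI, n = 4). A further injured group is labelled as lacking STAT3, a transcription factor of cytokine signalling, in astrocytes (STAT3-CKO SCI, n = 3). An uninjured STAT3-CKO group was not analysed here. With an HA IP and a flow-through library from each of 11 animals, there were 22 libraries in 6 groups. The comparisons ask what injury, and loss of STAT3 after it, change in HA IP RNA and which of these differences flow-through shows.

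HA IP libraries held 37267334 to 59337089 counts in uninjured, 31574207 to 46055612 in WT SCI and 31292491 to 37970557 in STAT3-CKO SCI animals. Flow-through libraries held 4904425 to 11242654, 3898755 to 7189443 and 4396861 to 8399656. Rn45s, the ribosomal RNA precursor, took 12.6% to 26.7% of the HA IP counts in uninjured, 89.0% to 96.2% in WT SCI and 52.2% to 89.2% in STAT3-CKO SCI libraries. In flow-through it took 9.49% to 39.7%, 89.0% to 95.5% and 50.0% to 88.4%. Outside Rn45s, Lars2 and Mir6236, whose counts are known to include ribosomal reads, HA IP libraries kept 26934866 to 51571785 counts in uninjured, 620265 to 2691494 in WT SCI and 2496641 to 17348247 in STAT3-CKO SCI animals. Flow-through libraries kept 2858044 to 10140612, 91626 to 615302 and 460759 to 4022328. The shallowest library, the flow-through of WT SCI animal 9935, puts 3 counts at 32.7 CPM of such counts. Low genes were measured least well in WT SCI flow-through. In both fractions the Rn45s share was higher in every injured than in every uninjured library, so injury and this share cannot be told apart in the comparisons with uninjured cord. Whether tissue, RNA quality or counting gave this share is not known from the labels or files.

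**Figure D1:**
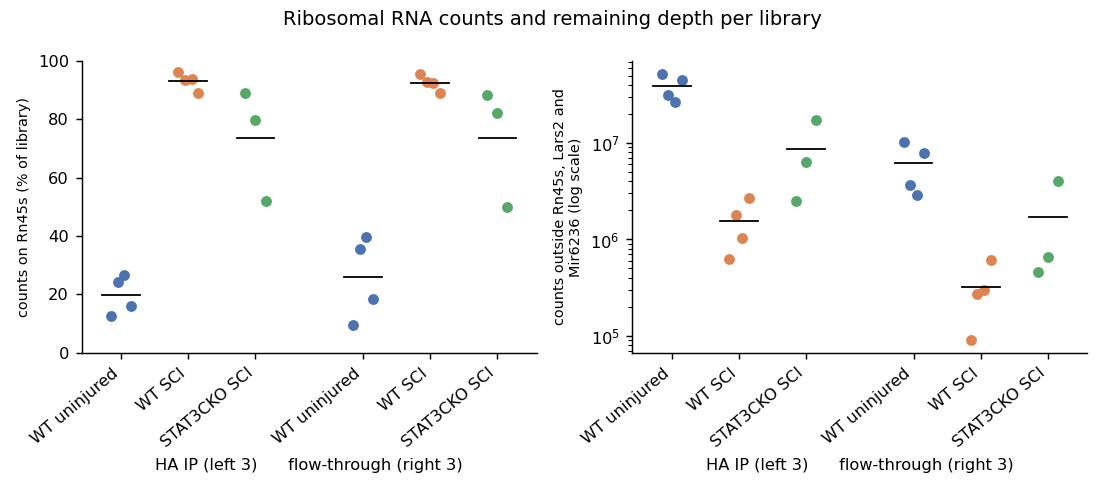
Share of counts on Rn45s (left, percent of library) and counts outside Rn45s, Lars2 and Mir6236 (right, counts on a log scale) for each library (points) with the group mean (line), HA IP groups left and flow-through groups right in each panel. WT SCI libraries sit at 89.0% or more Rn45s in both fractions, and uninjured libraries at 39.7% or less.

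Stat3, the targeted gene (chromosome 11, 100885098 to 100939540, minus strand, GRCm38), was lower in HA IP of STAT3-CKO SCI than of WT SCI in every library. HA IP levels were 12.2, 14.2, 15.5 and 13.3 CPM in uninjured animals 42, 79, 65 and 154. They were 66.15, 56.2, 26.3 and 35.0 CPM in WT SCI animals 9935, 9874, 9843 and 9596, and 7.85, 10.1 and 12.3 CPM in STAT3-CKO animals 186, 531 and 270. Flow-through levels were 11.6, 11.35, 14.2 and 13.6 CPM, then 17.7, 28.65, 29.5 and 59.6 CPM, then 14.2, 24.85 and 27.3 CPM in the same order. HA IP Stat3 rose by 1.73 ± 0.30 (log2 ± SE, adjusted p = 0.000373) from 13.8 ± 1.41 CPM (SD, n = 4) in uninjured to 45.9 ± 18.4 CPM (n = 4) in WT SCI. It was 10.1 ± 2.24 CPM (n = 3) in STAT3-CKO SCI, a log2 difference of −2.17 ± 0.34 from WT SCI (adjusted p = 0.00331) and −0.44 ± 0.32 from uninjured (adjusted p = 0.452). In flow-through it rose by 1.48 ± 0.34 with injury in WT (adjusted p = 0.00137; 0.94 with adjusted p = 0.0749 when thinned to equal depth). It did not pass the test between genotypes (−0.66 ± 0.37, adjusted p = 0.441). The counts cover the whole gene and the labels do not give the deleted exons, so they check the genotype labels only in part.

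Astrocyte genes were higher in the HA IP than in the flow-through of uninjured cord, with 19 of 20 homeostatic members called. Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912, minus strand), was 5.12 ± 0.22 (log2 ± SE) above flow-through (3838 ± 791 against 110 ± 19.8 CPM, SD, n = 4 each). The gap junction gene Gja1 (4.93 ± 0.20), the glutamate transporter Slc1a2 (4.76 ± 0.58), the folate enzyme Aldh1l1 (4.50 ± 0.26) and the water channel Aqp4 (4.32 ± 0.21) were likewise higher. The 20 homeostatic astrocyte genes had a median of 4.25 (19 called adjusted over the list alone). In turn, 14 of 15 neuron markers were lower (14 over the list alone, median −2.18), among them the synaptic genes Snap25 (−2.22 ± 0.24) and Syt1 (−2.07 ± 0.29). Microglia and macrophage markers were lower for 10 of 16 and higher for 1 (12 and 1 over the list alone, median −1.39). Myelin genes were lower for 10 of 13 (11 over the list alone, median −0.69). Markers of some other cells were higher in HA IP: 9 of 10 OPC genes, with 1 lower (the same over the list alone, median 1.44), and 8 of 9 ependymal genes (9 over the list alone, median 2.07).

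The genes with the largest excess in HA IP were Rarres1 (6.86 ± 0.64), the Wnt ligand Wnt7a (5.57 ± 0.43), Pgm5 (5.48 ± 0.24) and Nat1 (5.40 ± 0.57). Next were the Hippo pathway effector Yap1 (5.20 ± 0.27), Heph (5.16 ± 0.39), Gfap and Bdh2 (5.11 ± 0.36). Those with the largest excess in flow-through were the RNase P RNA Rpph1 (−2.51 ± 0.42), Rltpr (−2.41 ± 0.25) and genes known from neurons. Among the last were the neuropeptides Sst (−2.45 ± 0.16), Calca (−2.43 ± 0.25) and Tac2 (−2.37 ± 0.25), and the acetylcholine transporter Slc18a3 (−2.37 ± 0.21). Of the fixed markers, Pdgfra (1.55 ± 0.19), Olig1 (1.76 ± 0.21), Col1a2 (2.42 ± 0.22), Ccdc153 (3.30 ± 0.50) and Foxj1 (0.95 ± 0.27) were higher in HA IP. P2ry12 (−1.21 ± 0.24) and Mbp (−1.09 ± 0.15) were lower. Cx3cr1 (−0.84, adjusted p = 0.111, or 0.00793 with animal as a block) and Col1a1 (−0.67, adjusted p = 0.158) did not pass. Pmp2 was 26.7-fold higher in HA IP with a 95% counting interval of 4.72 to 1060, from 142 counts against 1. The test called 7250 of 14312 genes, 3780 higher and 3470 lower in HA IP (3625 and 3627 with RLE scaling, 3916 and 3952 with DESeq2). It called 3369 when all 22 libraries shared 1 fit, where P2ry12 (adjusted p = 0.0788) and Foxj1 (0.146) lost their calls. The small excess of Stat3 in HA IP (0.38 ± 0.14, adjusted p = 0.0356) was lost with RLE scaling (0.0545), and in the 22-library fit (0.55). It was also lost without the HA IP library of animal 79 (0.0797), 65 (0.109) or 154 (0.0955) or the flow-through of animal 42 (0.0577) or 79 (0.0807).

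**Figure D2:**
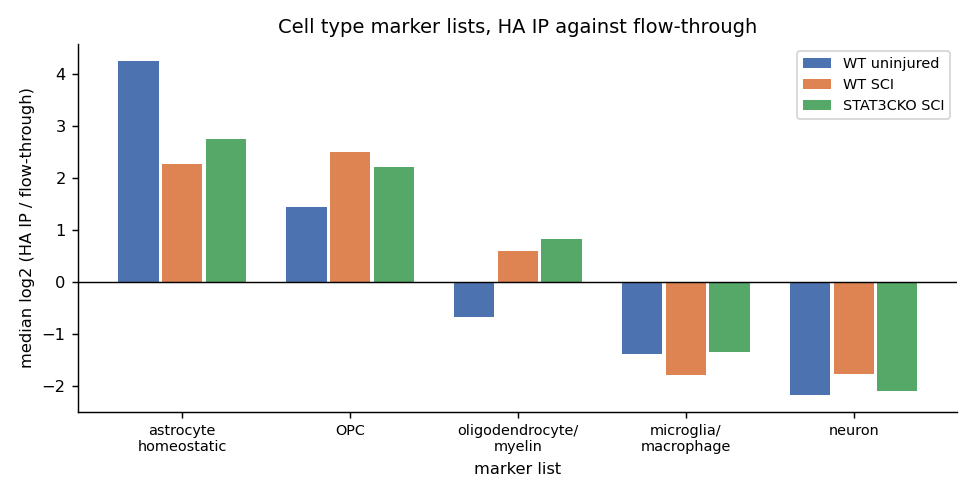
Median log2 ratio of HA IP over flow-through for the tested members of 5 marker lists (horizontal axis), in uninjured, WT SCI and STAT3-CKO SCI tissue (bars). Homeostatic astrocyte genes have medians of 4.25, 2.26 and 2.74, and neuron markers −2.18, −1.78 and −2.11.

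HA IP of injured WT cord held more RNA of pan-reactive astrocyte genes, which rose for 9 of 13, and less of cholesterol synthesis genes, which fell for 11 of 16. Both list calls held with an estimated correlation (adjusted p = 0.0217 and 0.0168). Vim, an intermediate filament gene of reactive astrocytes, rose by 3.23 ± 0.27 (log2 ± SE, adjusted p = 2.93e-07) from 15.7 ± 3.30 to 147 ± 37.2 CPM (SD, n = 4 each). Gfap rose by 1.62 ± 0.28 (adjusted p = 0.000341) from 746 ± 169 to 2291 ± 671 CPM, and the metalloproteinase inhibitor Timp1 by 7.76 ± 0.47 from 0.371 ± 0.0902 to 80.9 ± 28.7 CPM. Socs3, a feedback inhibitor of STAT3 signalling, rose by 4.83 ± 0.73 and the secreted lipocalin Lcn2 by 8.59 ± 1.22. Genes known from phagocytes rose too, among them Lyz2 (8.98 ± 0.53), Cst7 (9.52 ± 0.82) and C1qa (6.77 ± 0.49). So did Trem2 (6.82 ± 0.58) and Gpnmb (6.71 ± 0.50). Gstm1, a glutathione transferase, was lower by a log2 of −3.55 ± 0.28 (47.8 ± 11.5 against 560 ± 122 CPM) and Acsl6, which activates long-chain fatty acids, by −3.68 ± 0.35.

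The pan-reactive list had a median of 4.13 (10 called adjusted over the list alone). A1 genes rose for 9 of 11 (9 over the list alone, median 2.98; adjusted p = 0.0217 with an estimated correlation), including the proteoglycan Srgn (5.37 ± 0.81) and the interferon-inducible GTPase Iigp1 (4.65 ± 0.61). STAT3 response genes rose for 10 of 17 (11 with 1 lower over the list alone, median 2.58; 0.0217). Cholesterol synthesis genes fell for 11 of 16 (13 over the list alone, median −1.71; 0.0168), with the isomerase Idi1 at −5.14 ± 0.60 and the dehydrogenase Nsdhl at −4.13 ± 0.53. Other list calls of camera were lost with an estimated correlation, whose adjusted p follows each list. A2 genes rose for 6 of 10 and fell for 1 (6 and 1 over the list alone; adjusted p = 0.336). Homeostatic astrocyte genes fell for 10 of 20 (11 over the list alone, median −0.82; adjusted p = 0.158). Interferon genes rose for 14 of 14 (14 over the list alone; adjusted p = 0.0759), led by the nucleic acid sensor Zbp1 (8.27 ± 1.11) and the GTPase Mx1 (7.56 ± 1.26). Antigen presentation genes rose for 9 of 12 (9 over the list alone; adjusted p = 0.137), led by the class II gene H2-Ab1 (6.24 ± 0.59) and the class I transactivator gene Nlrc5 (5.58 ± 0.94). Cell cycle genes rose for 10 of 15 (11 over the list alone; adjusted p = 0.125), chemokines and cytokines for 10 of 14 with 1 lower (11 and 1; adjusted p = 0.103). Immediate early genes rose for 7 of 10 (7; adjusted p = 0.0969) and chondroitin sulfate synthesis genes for 4 of 14 with 1 lower (4 and 1; adjusted p = 0.226).

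Genes that act on axon growth moved both ways. Axon growth permissive genes rose for 14 of 30 and fell for 2 (14 and 4 adjusted over the list alone; adjusted p = 0.0691 with an estimated correlation). The matrix protein Fn1 rose by 5.49 ± 0.66 and the growth factor Igf1 by 5.29 ± 0.45. The adhesion genes Sdc2 (−1.17 ± 0.31) and Ncam1 (−1.0 ± 0.29) were lower. Axon growth inhibitory genes rose for 3 of 27 and fell for 4 (3 and 4 over the list alone; camera adjusted p = 0.998). The matrix gene Tnr rose by 1.93 ± 0.27 and the guidance receptor Epha4 was lower (−1.58 ± 0.45). The list's median (0.06) and mean (−0.44) differ in sign. Sema3f, a repulsive guidance cue, had 0 counts in WT SCI and 212 in uninjured libraries, at least 2.32-fold lower. CSPG core proteins, the protein parts of these matrix proteoglycans, rose for 3 of 7 and fell for 2, also adjusted over the list alone. Those higher were Cspg4 by 2.31 ± 0.32, Cspg5 by 1.82 ± 0.29 and Vcan by 1.41 ± 0.35, and those lower Ncan (−1.15 ± 0.30) and Ptprz1 (−1.23 ± 0.29). Bcan (−0.29, adjusted p = 0.49) and Acan (−0.86, adjusted p = 0.439) did not pass. The list's median (−0.29) and mean (0.29) differ in sign and its test did not pass (camera adjusted p = 0.472). Aqp4 was lower (−0.76 ± 0.25, adjusted p = 0.0289) and Aldh1l1 did not pass (0.19 ± 0.35, adjusted p = 0.719).

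Markers of other cells moved in the same libraries: microglia and macrophage markers rose for 16 of 17 (16 with 1 lower adjusted over the list alone, median 4.54; adjusted p = 0.0533 with an estimated correlation), led by Ms4a7 (9.20 ± 0.98) and Lyz2. OPC markers rose for 8 of 10 with 1 lower (8 and 1 over the list alone; adjusted p = 0.0712). Myelin genes rose for 8 of 13 with 1 lower (8 and 2; adjusted p = 0.071). Neuron markers fell for 7 of 15 (7; adjusted p = 0.414; median −1.18, or −1.08 with members at 0 counts set to their bound). Fewer members of the remaining lists were called: 4 of 8 complement (4 with 1 lower over the list alone), 2 of 6 endothelial (3), 3 of 11 fibroblast and pericyte (4), 1 of 7 Schwann cell (1) and 2 of 9 ependymal (2) genes rose. Their camera adjusted p were 0.0814, 0.391, 0.15, 0.971 and 0.59. The 1 lymphocyte marker tested was not called, and 0 blood genes were abundant enough to be tested in any of the 6 within-fraction comparisons. Sprr1a, a gene induced in injured neurons, rose by 7.53 ± 0.70, and the ribosomal-read-bearing Lars2 by 6.61 ± 0.64. Further large falls were those of the glucocorticoid-activating enzyme Hsd11b1 (−4.67 ± 0.77) and the GABA receptor subunit Gabrg1 (−3.64 ± 0.51).

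The test called 3938 of 14764 genes, 2331 higher and 1607 lower in WT SCI (5858 at an unadjusted p under 0.05), and 1936 higher and 2041 lower with only these groups in the fit. Rn45s took 89.0% to 96.2% of the WT SCI and 12.6% to 26.7% of the uninjured counts. WT SCI animal 9874 stood above the other 3 in H2-Ab1 (20.9 against 3.26 to 4.88 CPM), Fn1 (51.4 against 5.90 to 11.7) and Ptprz1 (54.4 against 28.0 to 30.9). Animal 9935 stood above them in Hsd11b1 (5.21 against 0.0686 to 0.872) and Gabrg1 (5.54 against 1.05 to 1.30) and below in Vim (91.9 against 161 to 173). The call of Aqp4 was lost without uninjured animal 42 (adjusted p = 0.093), 65 (0.0718) or 154 (0.0508) or WT SCI animal 9843 (0.0605). That of Epha4 was lost without uninjured animal 42 (0.0533), and that of Sema3f without any 1 of the 8 libraries (0.0537 to 0.0985) or with no filter (0.0662).

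HA IP of injured STAT3-CKO cord held less RNA of pan-reactive astrocyte genes than that of injured WT cord, with 7 of 13 lower (adjusted p = 0.014 with an estimated correlation). Antigen presentation genes were higher for 5 of 12, and that list's call was lost with an estimated correlation (adjusted p = 0.106). Timp1 (chromosome X, 20870166 to 20874735, plus strand) was 35.5-fold lower (log2 −5.15 ± 0.48, adjusted p = 1.15e-05; 2.32 ± 1.27 CPM, SD, n = 3, against 80.9 ± 28.7, n = 4). The small heat shock gene Hspb1 was 32.8-fold lower (−5.03 ± 0.42) and the protease inhibitor Serpina3n 18.9-fold (−4.24 ± 0.43; 39.0 ± 23.7 against 737 ± 243 CPM). Gfap was 4.39-fold lower (−2.13 ± 0.32, adjusted p = 0.00247; 522 ± 159 against 2291 ± 671 CPM). Cd74, the class II invariant chain (chromosome 18, 60803848 to 60812652, plus strand), was 14.6-fold higher (3.86 ± 0.49, adjusted p = 0.0006; 182 ± 100 against 12.2 ± 9.58 CPM) and the class II gene H2-Aa 14.7-fold (3.88 ± 0.60). Ncan, the proteoglycan neurocan (chromosome 8, 70093085 to 70120873, minus strand), was 5.19-fold higher (2.38 ± 0.32, adjusted p = 0.00086; 148 ± 49.2 against 28.3 ± 11.2 CPM). Rn45s took 52.2% to 89.2% of counts in these STAT3-CKO and 89.0% to 96.2% in these WT SCI libraries.

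The pan-reactive list had a median of −2.79 (9 called adjusted over the list alone). Lcn2 stood at −6.03 ± 1.26 and the asparaginase Aspg at −6.53 ± 1.40, while Vim did not pass (−1.04 ± 0.28, adjusted p = 0.0731). STAT3 response genes were lower for 3 of 17, Timp1 and Socs3 (−4.12 ± 0.83) among them (7 lower and 2 higher over the list alone, median −1.51; adjusted p = 0.0316 with an estimated correlation). Of the A2 genes 2 of 10 were lower (3 over the list alone; adjusted p = 0.249 with an estimated correlation), namely the transglutaminase Tgm1 (−6.53 ± 0.99) and the pentraxin Ptx3 (−5.43 ± 1.10). Of complement genes 2 of 8 were lower with C3 (−3.08 ± 0.41) among them (2 over the list alone; camera adjusted p = 0.0662). That list's median was 0.37 and its mean −0.32. Antigen presentation genes had a median of 1.91 (10 called over the list alone; camera adjusted p = 1.83e-07, or 0.106 with an estimated correlation). Of the microglia and macrophage markers, cells that also make these transcripts, edgeR called 0 of 17 (0 over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2; median 0.08; camera adjusted p = 0.971). A1 genes were higher for 2 of 11 (2 over the list alone; camera adjusted p = 0.331), with Iigp1 at 4.05 ± 0.59. Of 20 homeostatic genes edgeR called 0, with 5 higher over the list alone and at an unadjusted p under 0.05 and 2 by DESeq2 (median 0.33; camera adjusted p = 0.0517). Aqp4 (0.88 ± 0.26, adjusted p = 0.107) and Aldh1l1 (−0.52 ± 0.38, adjusted p = 0.514) did not pass.

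CSPG core proteins were higher for 2 of 7, Ncan and Bcan (1.43 ± 0.31, adjusted p = 0.0306), with 5 higher and 1 lower adjusted over the list alone (median 1.20; adjusted p = 0.081 with an estimated correlation). Ptprz1 (1.20, adjusted p = 0.0622), Vcan (0.89, adjusted p = 0.242), Acan (2.16, adjusted p = 0.206), Cspg4 (0.50, adjusted p = 0.456) and Cspg5 (−1.07, adjusted p = 0.1) did not pass. These 2 were also the axon growth inhibitory genes called, of 27 tested (5 over the list alone; adjusted p = 0.0958 with an estimated correlation; median 0.43, or 0.42 with bounds). EdgeR called 0 of 30 axon growth permissive genes (1 higher and 2 lower over the list alone, 5 and 5 at an unadjusted p under 0.05, 1 and 4 by DESeq2; camera adjusted p = 0.892). The smallest p was that of the matrix gene Tnc (2.49 ± 0.71, adjusted p = 0.0935). Also called were 1 of 7 Schwann cell genes (higher, 3 over the list alone; adjusted p = 0.0712 with an estimated correlation). So were 1 of 16 cholesterol synthesis genes (higher, 2 over the list alone; median −0.31, mean 0.02) and 1 of 13 myelin genes (lower, 2 over the list alone). EdgeR called 0 interferon genes of 14 tested (2 higher at an unadjusted p under 0.05, 0 by DESeq2) and 0 of 14 chemokine and cytokine genes (1 higher and 2 lower unadjusted, 2 lower by DESeq2). It called 0 of 14 chondroitin sulfate synthesis genes (2 higher and 3 lower unadjusted, 1 lower by DESeq2, 1 lower over the list alone) and 0 of 10 immediate early genes (1 lower unadjusted and by DESeq2). It also called 0 of 15 cell cycle, 10 OPC, 15 neuron, 11 fibroblast, 6 endothelial, 9 ependymal and 1 lymphocyte gene. Of these 1 neuron and 2 fibroblast genes were higher and 1 neuron and 1 ependymal gene lower at an unadjusted p under 0.05 and DESeq2 called 0. Other genes with large differences were the interferon-inducible GTPase Irgm2 (2.81 ± 0.36), Ly6a (3.06 ± 0.65), the matrix gene Egfl6 (2.88 ± 0.55), Heyl (2.81 ± 0.54) and the agrin receptor Lrp4 (2.54 ± 0.47), all higher. The F-box gene Fbxw9 (−3.75 ± 0.82), Igfbp7 (−3.30 ± 0.51), the collagen-binding fibromodulin Fmod (−3.12 ± 0.40) and the kinase Mylk (−2.89 ± 0.44) were lower.

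The test called 171 of 14764 genes, 88 higher and 83 lower (2422 at an unadjusted p under 0.05), 917 with DESeq2 (421 and 496) and 36 with only these groups in the fit (11 and 25). More were lower also with RLE scaling (79 and 98), thinned (58 and 87), without WT SCI animal 9843 (111 and 126) and without STAT3-CKO animal 531 (18 and 21). The count was 39 without STAT3-CKO animal 531, 57 without 270, 91 without 186, 343 without WT SCI animal 9596 and 295 without 9935. Calls were lost without STAT3-CKO animal 186 for Aspg, Bcan, Egfl6, Fbxw9, Heyl, Lcn2, Ly6a, Ptx3 and Socs3 (adjusted p 0.0531 to 0.123). Without 531 they were lost for Aspg, Bcan, Fbxw9, Heyl, Lcn2, Lrp4, Ly6a, Ptx3 and Socs3 (0.0648 to 0.148), and without 270, the one STAT3-CKO library with counts of Aspg (8) or Lcn2 (30), for Aspg, Egfl6, Fbxw9, Ly6a, Ptx3 and Socs3 (0.0648 to 0.163). They were also lost for Bcan without WT SCI animal 9843 (0.0508), Lcn2 without 9874 (0.0514) and Fbxw9 without 9596 (−1.86, 0.0734). With only these groups in the fit they were lost for Bcan, Egfl6, Fbxw9, Heyl, Lrp4, Ly6a, Ptx3 and Socs3 (0.0618 to 0.153). Within WT SCI, animal 9596 stood above the others in Fbxw9 (134 against 8.02 to 15.6 CPM) and animal 9874 in Ly6a and Tgm1. Among uninjured HA IP libraries, animal 42 was low in Serpina3n and animal 154 in Mylk.

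**Figure D3:**
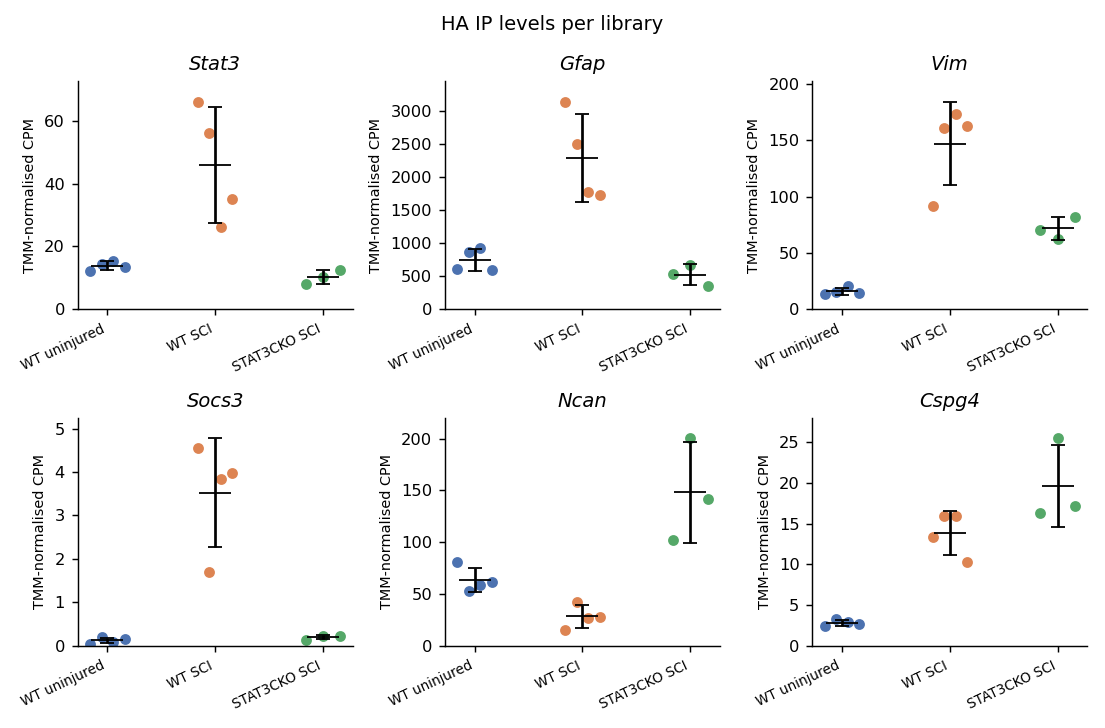
HA IP levels of 6 genes in TMM-normalised CPM for each library (points) with the group mean and SD (bars), in uninjured (n = 4), WT SCI (n = 4) and STAT3-CKO SCI (n = 3) animals. Gfap averages 746, 2291 and 522 CPM and Ncan 63.5, 28.3 and 148 CPM across these groups.

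Against HA IP of uninjured cord, that of injured STAT3-CKO cord held more RNA of antigen presentation genes, which rose for 11 of 12, and of CSPG core proteins, which rose for 4 of 7. Both list calls held with an estimated correlation (adjusted p = 0.0295 and 0.0386). Cd74 rose by 9.02 ± 0.61 (log2 ± SE, adjusted p = 4.73e-08) from 0.349 ± 0.0512 CPM (SD, n = 4) to 182 ± 100 (n = 3). H2-Ab1 rose by 8.72 ± 0.66, H2-Aa by 8.43 ± 0.70 and Iigp1 by 8.70 ± 0.69. Vim rose by 2.19 ± 0.27 (71.7 ± 9.84 against 15.7 ± 3.30 CPM). Gfap (−0.51 ± 0.30, adjusted p = 0.337), Aqp4 (0.12, adjusted p = 0.831), Aldh1l1 (−0.33, adjusted p = 0.66), Socs3 (0.71, adjusted p = 0.617) and Lcn2 (2.56, adjusted p = 0.17) did not pass. Insig1, a regulator of sterol synthesis, was lower (−3.11 ± 0.36), as were the sterol genes Mvd (−2.78 ± 0.51) and Msmo1 (−2.56 ± 0.47) and the complement gene C3 (−2.71 ± 0.40).

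The antigen presentation list had a median of 5.01 (12 called adjusted over the list alone). A1 genes rose for 8 of 11 (8 over the list alone, median 3.48; adjusted p = 0.014 with an estimated correlation), with the class I gene H2-T23 at 5.14 ± 0.47. Axon growth permissive genes rose for 11 of 30 (13 over the list alone; 0.0275), with Igf1 at 5.56 ± 0.46 and Fn1 at 4.85 ± 0.65. The CSPG core proteins that rose (5 over the list alone, median 1.22) were Cspg4 (2.82 ± 0.34), Vcan (2.30 ± 0.37), Ncan (1.22 ± 0.31) and Bcan (1.15 ± 0.31). Acan (1.30, adjusted p = 0.314), Cspg5 (0.75, adjusted p = 0.138) and Ptprz1 (−0.03, adjusted p = 0.969) did not pass. STAT3 response genes rose for 3 of 17 (9 over the list alone; 0.0275), immediate early genes for 4 of 10 (4; 0.0295), and cholesterol synthesis genes fell for 11 of 16 (13 over the list alone, median −2.14; 0.00943). Pan-reactive genes rose for 3 of 13 and fell for 1, also over the list alone, and the list did not pass (camera adjusted p = 0.114, median 0.77). Calls of camera lost with an estimated correlation were those of the interferon list, up for 14 of 14 (14 over the list alone; adjusted p = 0.0512; Zbp1 7.44 ± 1.08, Mx1 7.24 ± 1.25), and the axon growth inhibitory list, up for 6 of 27 (8; adjusted p = 0.148; Tnr 2.35 ± 0.28). Also lost were those of the homeostatic list, down for 5 of 20 (6; adjusted p = 0.145), the cell cycle list, up for 7 of 15 (13; adjusted p = 0.0958), and chemokines and cytokines, up for 10 of 14 (11 with 1 lower; adjusted p = 0.0675). Among the last, Ccl2 rose by 6.37 ± 1.25 and Ccl4 had 275 counts against 1, a ratio of 1610 with a 95% counting interval of 287 to 63900.

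Markers of other cells moved here too: microglia and macrophage markers rose for 16 of 17 (16 adjusted over the list alone, median 4.52; adjusted p = 0.0282 with an estimated correlation). Cst7 stood at 10.15 ± 0.84, Lyz2 at 8.30 ± 0.53, Ms4a7 at 9.18 ± 0.98 and Gpnmb at 6.79 ± 0.51. OPC markers rose for 6 of 10 (6 over the list alone; 0.0469) and myelin genes for 7 of 13 (8; 0.0469). Sprr1a rose by 7.85 ± 0.71, and Itih3 (−3.05 ± 0.46) and Gstm1 (−2.44 ± 0.30) were lower. The test called 1444 of 14764 genes, 1137 higher and 307 lower (3356 at an unadjusted p under 0.05). Rn45s took 52.2% to 89.2% of the STAT3-CKO and 12.6% to 26.7% of the uninjured counts. DESeq2 called 2254, a fit of only these groups 3585, and the thinned counts 948 of the 9525 genes then tested. Without uninjured animal 42, 79, 65 or 154 the counts were 909, 875, 906 and 848, and without STAT3-CKO animal 531 the count was 893. WT SCI animal 9596 stood above its group in Insig1 and Mvd. Lcn2, Cst7, Mx1 and Ccl4 were at 0.0735 CPM or less in every uninjured HA IP library, with 1 library apart in each. The call of Bcan was lost without uninjured animal 42 (adjusted p = 0.0818), 79 (0.0535) or 154 (0.0917) or STAT3-CKO animal 186 (0.176) or 531 (0.0857). That of Ncan was lost without uninjured animal 79, 65 or 154 or STAT3-CKO animal 531 (0.0561 to 0.138).

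**Figure D4:**
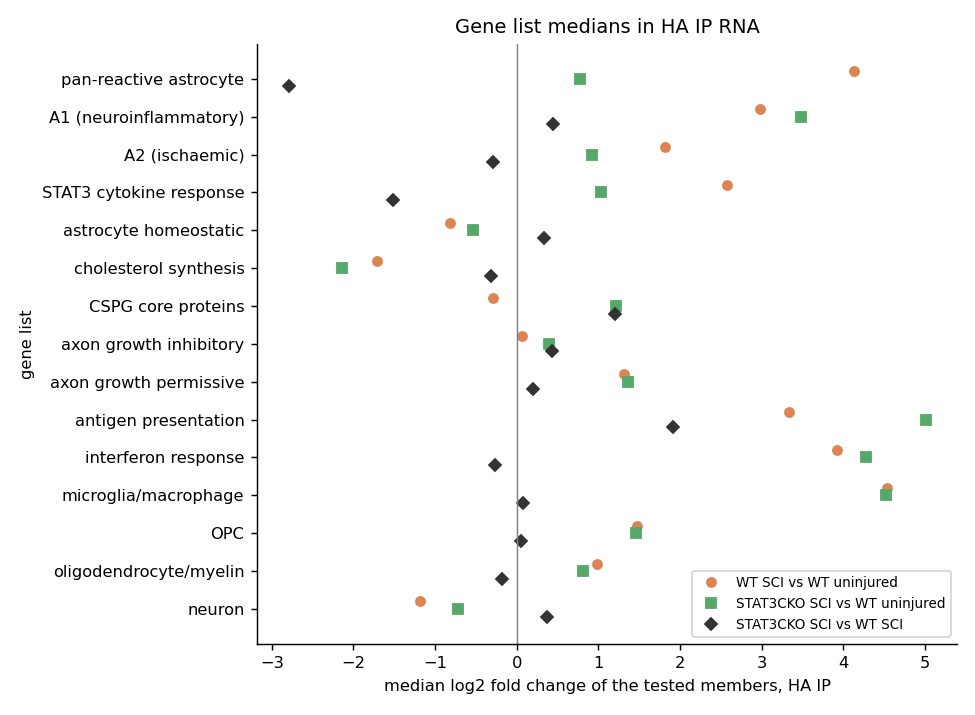
Median log2 fold change in HA IP over the tested members of 15 gene lists (vertical axis) for WT SCI against uninjured (circles), STAT3-CKO SCI against uninjured (squares) and STAT3-CKO SCI against WT SCI (diamonds). The pan-reactive medians are 4.13, 0.77 and −2.79, and the antigen presentation medians 3.34, 5.01 and 1.91.

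Flow-through of injured WT cord held more RNA of microglia and macrophage markers than that of uninjured cord, with 16 of 17 higher (adjusted p = 0.0295 with an estimated correlation). Neuron markers fell for 10 of 14, and that list's call was lost with an estimated correlation (adjusted p = 0.114). Gpnmb, a glycoprotein gene of phagocytes, rose by 10.36 ± 0.56 (log2 ± SE, adjusted p = 4.84e-13) from 0.464 ± 0.204 to 614 ± 434 CPM (SD, n = 4 each). The galectin Lgals3 rose by 10.05 ± 0.56 and the oxidase subunit Cybb by 9.17 ± 0.57. The macrophage lectin Siglec1 was at least 1460-fold higher and the apolipoprotein gene Apoc4 at least 749-fold, each with 0 counts in uninjured libraries. The potassium channel partners Kcnip4 (−4.81 ± 0.66) and Kcnip1 (−3.81 ± 0.53), and the neuronal calcium sensor Hpca (−4.51 ± 0.80) were lower. The microglia and macrophage list had a median of 4.86 (16 called adjusted over the list alone). Pan-reactive genes rose for 8 of 10 (9 over the list alone, median 3.53; adjusted p = 0.014 with an estimated correlation), with Timp1 at 6.17 ± 0.97 and the chemokine Cxcl10 at 8.79 ± 0.83. STAT3 response genes rose for 10 of 16 (13; 0.022) and A1 genes for 7 of 9 (7; 0.045), with Gbp2 at 5.98 ± 1.03 and the immunoproteasome subunit Psmb8 at 5.07 ± 0.70.

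Several camera calls here were lost with an estimated correlation. Antigen presentation genes rose for 10 of 11 (10 adjusted over the list alone; adjusted p = 0.0706; Nlrc5 7.19 ± 1.04, Tap1 6.61 ± 0.76) and interferon genes for 11 of 11 (11; adjusted p = 0.0886; Bst2 8.96 ± 0.48). Chemokines rose for 8 of 12 with 1 lower, Cx3cl1 (−1.65 ± 0.44; 9 and 1 over the list alone; adjusted p = 0.101). Homeostatic astrocyte genes rose for 10 of 20 (10, median 1.11; adjusted p = 0.219) and fibroblast genes for 5 of 8 (5; adjusted p = 0.297). Neuron markers had a median of −1.77 (10 called over the list alone), and cholesterol synthesis genes fell for 9 of 16 (10; adjusted p = 0.0512). With few counts in 1 group, the ratios were 10500 for Cst7 (95% counting interval 1880 to 417000), 2020 for Ms4a7 (352 to 80700), 820 for Wfdc17 (218 to 6920) and 934 for Ccl4 (157 to 37900). Zbp1 was at least 572-fold higher. The glycosyltransferase Extl2 (−4.73 ± 0.55) and Gsta4 (−4.13 ± 0.61) were lower as well. The test called 3933 of 12685 genes, 2120 higher and 1813 lower (5278 at an unadjusted p under 0.05), and 1332 of the 2903 genes left to test when thinned to equal depth. More were lower with RLE scaling (1903 higher and 2085 lower), DESeq2 (2154 and 2291) and only these groups in the fit (1611 and 2001). Rn45s took 89.0% to 95.5% of the WT SCI and 9.49% to 39.7% of the uninjured counts. In uninjured flow-through, Cst7, Ms4a7, Wfdc17, Nlrc5, Cxcl10, Timp1 and Ccl4 had counts in 1 animal each, animal 42 was low in Gsta4 and animal 65 high in Gbp2.

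Few flow-through genes of injured cord were called between genotypes, with 7.5% recovery at a simulated log2 change of 1. Gfap (−2.47 ± 0.31, adjusted p = 0.000105; 61.7 ± 21.5 CPM, SD, n = 3, against 340 ± 41.8, n = 4) and Serpina3n (−2.45 ± 0.30, adjusted p = 0.000105) were lower in STAT3-CKO SCI. So were the protease inhibitor A2m (−3.41 ± 0.58) and Nudt6 (−2.62 ± 0.54), named after its value was seen. Cd74 was higher (2.21 ± 0.41, adjusted p = 0.0245; 214.5 ± 122 against 45.2 ± 27.1 CPM). Higher too were the neuronal genes Snap25 (1.58 ± 0.29), Penk (1.74 ± 0.32), Syngr3 (2.32 ± 0.48) and Kcng4 (2.64 ± 0.51). So were Extl2 (3.38 ± 0.59), Micu3 (2.38 ± 0.49), Ppm1e (2.33 ± 0.46) and Hspa4l (2.06 ± 0.39). Pan-reactive genes were lower for 2 of 10 (5 adjusted over the list alone, median −1.51; adjusted p = 0.0154 with an estimated correlation). Camera calls lost with an estimated correlation were antigen presentation, higher for 1 of 11 (5 over the list alone; adjusted p = 0.438), and neuron markers, higher for 1 of 14 (4 over the list alone; adjusted p = 0.231). So was that of immediate early genes, higher for 1 of 10, the synaptic gene Arc (adjusted p = 0.0408), also named after its value was seen (4 over the list alone; adjusted p = 0.0969; median 0.80, or 0.27 with bounds). The others were microglia, myelin, homeostatic and interferon genes, whose lists were placed lower with 0 members called by edgeR (adjusted p = 0.433, 0.226, 0.333 and 0.389). At an unadjusted p under 0.05, 2 microglia, 4 myelin, 1 homeostatic and 4 interferon genes were lower and 1 myelin and 1 homeostatic gene higher. DESeq2 called 2 myelin genes lower and 1 higher.

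The test called 15 of 12685 genes, 11 higher and 4 lower (1665 at an unadjusted p under 0.05), 213 with DESeq2, 131 with no filter, 4 with only these groups in the fit (all lower) and 19 when thinned (9 and 10). The count was 2 without STAT3-CKO animal 270, 3 without 531 or 186, 5 without WT SCI animal 9843 and 29 without 9596, with more lower than higher in the first 4. Gfap and Serpina3n kept their calls in each of those fits, and the genes below lost theirs in some. With only these groups in the fit the adjusted p was 0.0942 to 0.321 for Cd74, Extl2, Hspa4l, Kcng4, Micu3, Penk, Ppm1e, Snap25 and Syngr3. Thinned to equal depth it was 0.26 for Hspa4l and 0.136 for Syngr3. RLE scaling ended the call of Syngr3 (0.0539), and leaving out the Rn45s, Lars2 and Mir6236 counts ended those of Micu3 and Syngr3 (0.0568). Without animal 270 the adjusted p was 0.0572 to 0.212 for A2m and the 9 genes above. Without 531 it was 0.0789 to 0.175 for these except Extl2, and without 186 it was 0.0546 to 0.133 for these except Cd74. WT SCI animals also mattered: 9843 (0.0504 to 0.105 for the 9 except Extl2), 9596 (0.0605 to 0.0753 for Hspa4l, Kcng4, Ppm1e and Syngr3), 9935 (0.0525 for Cd74 and Micu3) and 9874 (0.0843 for Micu3 and 0.0661 for Ppm1e). Animal 9935 was high in Kcng4.

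Flow-through of injured STAT3-CKO cord also held more RNA of microglia and macrophage markers than that of uninjured cord, with 16 of 17 higher (adjusted p = 0.0217 with an estimated correlation). Neuron markers fell for 5 of 14, and that list's call was lost with an estimated correlation (adjusted p = 0.101). Gpnmb rose by 10.25 ± 0.57 (log2 ± SE, adjusted p = 7.97e-13; 568 ± 127 CPM, SD, n = 3, against 0.464 ± 0.204, n = 4). Lgals3 rose by 10.18 ± 0.56, Cybb by 9.41 ± 0.58 and H2-Ab1 by 7.53 ± 0.58. The synaptic gene Snap25 was lower (−2.13 ± 0.31; 420.5 ± 90.8 against 1848 ± 240 CPM). Lower too were Tac2 (−3.20 ± 0.50), Hpca (−2.29 ± 0.61), Trp53i11 (−2.23 ± 0.46) and the calcium sensor Vsnl1 (−2.21 ± 0.34). Over the list alone, 16 microglia and macrophage markers were called. Antigen presentation genes rose for 10 of 11 (10 over the list alone; adjusted p = 0.0284 with an estimated correlation; Nlrc5 7.16 ± 1.02). A1 genes rose for 7 of 9 (7; 0.0282; Gbp2 7.84 ± 0.91, Psmb8 4.91 ± 0.70), STAT3 response genes for 7 of 16 (8; 0.0217) and pan-reactive genes for 6 of 10 (6; 0.024). Cholesterol synthesis genes fell for 10 of 16 (10; 0.0217; Idi1 −3.03 ± 0.85).

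Lost with an estimated correlation were the calls of interferon genes, up for 10 of 11 (11 adjusted over the list alone; adjusted p = 0.0712; Bst2 8.03 ± 0.48), and chemokines, up for 9 of 12 (10 with 1 lower; adjusted p = 0.0512; Cxcl10 8.95 ± 0.82). So was that of homeostatic astrocyte genes, up for 8 of 20 (13; adjusted p = 0.254). Over the list alone, 10 neuron markers were lower. Ratios over few counts were 12900 for Cst7 (95% counting interval 2320 to 511000), 3010 for Ms4a7 (538 to 119000) and 512 for Ccl4 (89.6 to 20400). Siglec1, Apoc4 and Zbp1 were at least 1330-fold, 526-fold and 318-fold higher. The test called 1769 of 12685 genes, 1321 higher and 448 lower (3285 at an unadjusted p under 0.05), 2751 with only these groups in the fit and 683 of the 2903 tested when thinned. Rn45s took 50.0% to 88.4% of the STAT3-CKO and 9.49% to 39.7% of the uninjured counts. The call of Idi1 was lost without STAT3-CKO animal 270 (adjusted p = 0.075) and that of Hpca with DESeq2 (0.169). Uninjured animal 42 was high in Trp53i11, and Idi1 had counts in 1 WT SCI flow-through library, that of animal 9874.

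After injury, homeostatic astrocyte genes were higher in HA IP than in flow-through for 16 of 20 members in WT SCI and 18 of 20 in STAT3-CKO SCI. In WT SCI, Gfap was 2.95 ± 0.31 (log2 ± SE) above flow-through (506 ± 163 against 65.8 ± 9.83 CPM, SD, n = 4 each). Gja1 stood at 2.84 ± 0.48, Aldh1l1 2.40 ± 0.57 and Slc1a2 1.99 ± 0.28, while Aqp4 did not pass (0.75 ± 0.27, adjusted p = 0.11, or 0.0182 with animal as a block). In STAT3-CKO SCI the values were 3.37 ± 0.37 for Gfap, 2.54 ± 0.39 for Gja1, 2.74 ± 0.46 for Aldh1l1, 3.21 ± 0.33 for Slc1a2 and 2.28 ± 0.35 for Aqp4. The homeostatic medians were 2.26 in WT SCI (17 called adjusted over the list alone) and 2.74 in STAT3-CKO SCI (18). Microglia and macrophage markers were lower in HA IP for 14 of 16 (16, median −1.80) and 13 of 17 (17, median −1.35), and neuron markers for 5 of 12 (10, median −1.78) and 13 of 14 (13, median −2.11). OPC markers were higher for 6 of 9 (9, median 2.49) and 7 of 9 (8, median 2.21), and myelin genes for 2 of 13 (4, median 0.58) and 4 of 13 (8, median 0.81).

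In WT SCI the large excesses in HA IP included those of the angiotensinogen gene Agt (3.84 ± 0.55), the chaperone clusterin Clu (3.40 ± 0.34), Bcan (3.34 ± 0.43) and the metallothioneins Mt2 (3.25 ± 0.30) and Mt1 (3.24 ± 0.31). Olig1 (2.68 ± 0.29) and Pdgfra (2.71 ± 0.49) were also higher. Flow-through held more of the myeloid genes Lyn (−2.23 ± 0.42), Cst7 (−2.12 ± 0.44), Tyrobp (−1.96 ± 0.45) and Cx3cr1 (−1.62 ± 0.40). It also held more of the neuronal genes Cdr1 (−2.16 ± 0.27) and Snap25 (−1.73 ± 0.34). In STAT3-CKO SCI, HA IP held more of the desaturase Fads2 (4.14 ± 0.34), the plexin Plxnb1 (4.06 ± 0.35), the amino acid transporter Slc7a10 (3.93 ± 0.45), the glypican Gpc5 (3.66 ± 0.44), Pdgfra (2.75 ± 0.35) and Olig1 (2.21 ± 0.37). Flow-through held more of the neuronal genes Cdr1 (−2.42 ± 0.40), Snap25 (−2.08 ± 0.36) and Syt1 (−1.89 ± 0.39). It also held more of the growth factor Igf2 (−2.32 ± 0.42), Col1a1 (−1.97 ± 0.52) and Cx3cr1 (−1.0 ± 0.29).

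Stat3 did not differ by the test between the fractions in WT SCI (0.61, adjusted p = 0.43) or STAT3-CKO SCI (−0.86, adjusted p = 0.133, or 0.0235 with animal as a block). The test called 529 of 8466 genes in WT SCI, 346 higher and 183 lower in HA IP (1741 at an unadjusted p under 0.05), and 1496 of 12659 in STAT3-CKO SCI, 901 higher and 595 lower (3141 unadjusted). With animal as a block, which the design pairs, the counts were 1096 and 3105. DESeq2 called 948 and the 22-library fit 1706 in WT SCI. The count in WT SCI was 324 without the flow-through of animal 9874 and 255 without that of 9843. In STAT3-CKO SCI it was 875 without the HA IP of animal 531, 802 without its flow-through and 971 without the flow-through of 270. In WT SCI the calls of Cst7 (adjusted p = 0.0605), Tyrobp (0.0708) and Cx3cr1 (0.106) were lost without the flow-through of animal 9874, which was high in Cst7. That of Tyrobp was lost also without that of 9843 (0.0726) and that of Cx3cr1 without that of 9935 (0.0525) or with no filter (0.0569). In STAT3-CKO SCI the call of Cx3cr1 was lost without any 1 library (0.0576 to 0.176) and that of Col1a1 without the HA IP of animal 531 (0.0925) or the flow-through of 270 (0.195). Those of Syt1 (0.0712) and Cx3cr1 (0.195) were lost in the 22-library fit.

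The injury change itself differed between the fractions for the lipoprotein lipase gene Lpl (HA IP minus flow-through −5.56 ± 0.58, log2 ± SE), the apolipoprotein gene Apoe (−5.27 ± 0.44), Lgals3 (−4.92 ± 0.72), the phagocytosis receptor Axl (−4.02 ± 0.39). It also differed for the class I gene H2-K1 (−3.77 ± 0.48) and the glutamate transporter Slc1a3 (−3.54 ± 0.53), and all of these rose less or fell more in HA IP. It was larger or less negative in HA IP for the G protein subunit Gng4 (3.81 ± 0.65), the oligodendrocyte protease Klk6 (3.67 ± 0.58), the neuronal glutamate transporter Slc1a1 (3.55 ± 0.60) and Magee2 (8.62 ± 1.96). The value of Magee2 rested on the HA IP of WT SCI animal 9874 (0.93, adjusted p = 0.831 without it). Homeostatic astrocyte genes had a lower change in HA IP for 10 of 20 (14 adjusted over the list alone, median −1.63). Myelin genes had a higher one for 10 of 13 (11, median 1.52), against a median of 0.262 over all genes tested, which was 0.065 with RLE scaling. The interaction was called for 713 of 15142 genes, 405 positive and 308 negative (2629 at an unadjusted p under 0.05), and 1934 with animal as a block. More were negative with DESeq2 (496 positive and 688 negative), RLE scaling (258 and 405) and without the Rn45s, Lars2 and Mir6236 counts (327 and 386).

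The genotype difference after injury differed between the fractions for 4 of 15142 genes (932 at an unadjusted p under 0.05; 13 with DESeq2, 8 of them positive, 31 with animal as a block, 1 with RLE scaling, positive). Leaving out the HA IP of animal 9874 or 270 or the flow-through of 9935, 9874 or 9843 gave 1, and leaving out the HA IP of 531 or the flow-through of 9596, 186, 531 or 270 gave 0. Serinc5, a membrane protein gene, had a higher change in HA IP (2.36 ± 0.40, log2 ± SE, adjusted p = 0.0201), and C3 (−3.05 ± 0.59, adjusted p = 0.0481) a lower one. So had Haus1 (−6.54 ± 1.25) and 2810408M09Rik (−5.72 ± 1.08), which fall outside the naming rule and were added after their values were seen. EdgeR called 0 of 12 antigen presentation genes (3 higher at an unadjusted p under 0.05) and 0 of 13 pan-reactive genes (3 lower unadjusted, 2 lower adjusted over the list alone), with 0 by DESeq2 in both lists. With animal as a block, Cd74 (1.76 ± 0.28, adjusted p = 0.0155) was called among the former and Serpina3n (−1.94 ± 0.29, adjusted p = 0.00835) among the latter. Stat3 did not pass (−1.52, adjusted p = 0.614). The call of Serinc5 was lost without the flow-through of WT SCI animal 9596 (adjusted p = 0.0865) or of STAT3-CKO animals 186 (0.0944), 531 (0.0588) and 270 (0.056), or the HA IP of 531 (0.0592). The call of C3 was lost without any 1 of 12 of the 14 libraries (0.0559 to 0.455), the others being the HA IP of WT SCI animals 9935 and 9596.

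Injury changes in HA IP of WT and STAT3-CKO mice, both taken against the same uninjured libraries, shared many genes. In all 990 of 14764 genes rose in both and 240 fell in both, where independent lists would share 179.5 and 33.4. The log2 changes correlated across genes at Pearson r = 0.64 (covariance 1.986), against 0.393 (0.153) in 20 simulations with no effect and the same shared libraries. With the uninjured libraries split into sets of 2, r was 0.613 and 447.5 and 70.7 genes were shared on average, against 38.75 and 4.317 for independent lists. The genotype difference ran against the injury change: of genes that rose in WT SCI, 71 were lower in STAT3-CKO SCI, and of genes that fell, 63 were higher (13.1 and 9.6 for independent lists). Here r was −0.76 (covariance −2.786) against −0.546 (−0.236) simulated, and −0.301 with the WT SCI libraries split into sets of 2. There 62 and 32.5 genes ran opposite on average (lowest 26 and 18), against 19.2 and 7.93 for independent lists. A technical trait of the WT SCI libraries, such as high Rn45s, could give this opposite pattern too. Genes are not independent, so these r carry no p.

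Genes higher in HA IP than in flow-through, in uninjured or WT SCI tissue, made up 33% of the genes whose HA IP level changed with injury in WT and 27% of the background of 14248 genes (1246 of 3781 against 3845 in all). The odds ratio was 1.488 (95% interval 1.371 to 1.615, Fisher's exact test, two-sided, p = 1.97e-21). They were 49.3% of the genes that fell (odds ratio 3.056) and 20.9% of those that rose (odds ratio 0.675, 95% interval 0.603 to 0.755). The last turned and was lost with genes higher in HA IP in both conditions (281 of 8396). There it was 1.152 (0.86 to 1.526, Fisher's exact test, p = 0.307). Both sets of calls use the same HA IP libraries, which can shift the odds ratios, and genes are not independent, so these p are too small. A test added after seeing the data shared no library. It took HA IP over flow-through from 2 uninjured animals and the injury change against the other 2. Its odds ratios over 6 halvings were 4.543 to 9.007 for genes that fell and 0.57 to 0.746 for genes that rose. No background was matched on level, so a role of abundance stays open.

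The authors' deposited tables list, at a false discovery rate under 0.05 by their own method, 5012 genes for injury in WT HA IP (2765 higher, 2247 lower). The authors' deposited tables also list 2367 for STAT3-CKO SCI against uninjured (1737 higher, 630 lower) and 712 for STAT3-CKO against WT SCI (407 higher, 305 lower). For flow-through the authors' deposited tables list 5036, 2910 and 244 genes, and for HA IP against flow-through 9960 in uninjured, 1981 in WT SCI and 3770 in STAT3-CKO SCI tissue.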

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

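Tests of technical explanations and counts over other splits were chosen only after the results were seen. Gap ratios within groups and differences between fractions were chosen beforehand.

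Of 248 gene and group values with 4 libraries, 30 had a gap ratio past Dixon's 95% critical value. The ratio is 1 library's gap to the nearest over the group's range. It is 1 wherever the others held 0 CPM, so 30 was not set against a chance rate. In HA IP of WT SCI, animal 9874 stood above the others in H2-Ab1 (gap ratio 0.908), Fn1 (0.873), Ptprz1 (0.892), Ly6a (0.841) and Tgm1 (0.875). Animal 9935 stood above them in Hsd11b1 (0.844) and Gabrg1 (0.943) and below in Vim (0.846), and animal 9596 above in Fbxw9 (0.939), Insig1 (0.865; 12.1 against 5.77 to 6.63 CPM) and Mvd (0.836; 13.4 against 3.62 to 5.23 CPM). In HA IP of uninjured cord, animal 42 was low in Serpina3n (0.83; 24.4 against 45.4 to 49.6 CPM) and animal 154 in Mylk (0.886; 2.98 against 5.00 to 5.26 CPM). Genes near 0 there had gap ratios of 0.839 (Cst7, animal 65, 0.0735 CPM), 0.848 (Mx1, animal 79, 0 CPM), 0.859 (Lcn2, animal 154, 0.0628 CPM) and 1 (Ccl4, animal 79, 0.00522 CPM). In uninjured flow-through, animal 42 was low in Gsta4 (0.837; 10.4 against 19.0 to 20.7 CPM) and high in Trp53i11 (0.904; 33.2 against 18 to 19.5 CPM). Low genes with counts in few libraries there were Cst7 (1; animal 154, 0.0201 CPM), Ms4a7 (1; animal 79, 0.0433 CPM), Wfdc17 (1; animal 154, 0.0401 CPM), Nlrc5 (1; animal 154, 0.0802 CPM), Cxcl10 (1; animal 79, 0.173 CPM), Timp1 (1; animal 42, 1.11 CPM), Ccl4 (1; animal 79, 0.0433 CPM) and Gbp2 (0.881; animal 65, 0.168 CPM). In WT SCI flow-through the ratios were 0.845 for Cst7 (animal 9874), 0.928 for Kcng4 (animal 9935) and 1 for Idi1 (animal 9874, 0.774 against 0 CPM).

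The injury change differed between HA IP and flow-through by an interaction test for 713 genes, with log2 differences of 8.62 for Magee2, 3.81 for Gng4, 3.67 for Klk6, 3.55 for Slc1a1, 3.52 for Olfm2, 3.50 for Tet3, 3.29 for Wwc1, 3.24 for Eml2, −5.56 for Lpl, −5.27 for Apoe, −4.92 for Lgals3, −4.02 for Axl, −3.77 for H2-K1, −3.72 for Acss1, −3.54 for Slc1a3 and −3.52 for Itga6. The genotype difference differed between the fractions for 4 genes, Serinc5 (2.36) and C3 (−3.05) among them.

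Homeostatic astrocyte genes stood at a median log2 ratio of 4.25 over flow-through in uninjured and 2.26 in WT SCI tissue. Flow-through RNA carried into the precipitate, as the whole cause, would hold microglia and neuron markers above a lowest ratio. Of these markers 27 of 28 lay below it with their 95% interval. A less complete precipitation and a change in the tissue cannot be told apart for the fall in HA IP (10 of 20 members, median −0.82) or the rise in flow-through (10 of 20, median 1.11). No library measures the yield, and at a lower yield untagged RNA of other cells could weigh more in HA IP, where microglia and macrophage markers had a median of 4.54. Injury itself stays open as a biological explanation, as does the Rn45s share, which separates the same libraries and was not tested apart from it.

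Pan-reactive genes were lower in HA IP of STAT3-CKO SCI than of WT SCI (median −2.79). A lower share of astrocyte RNA would lower homeostatic astrocyte genes alike, and 20 of 20 of these lay above the pan-reactive median with their 95% interval. Depth was tested by thinning all libraries to the shallowest, after which 6 of 9 tested members were called lower (median −4.10). Loss of STAT3 may account for part of the pattern, as a hypothesis that stays open: the share of Rn45s differs with genotype, and no uninjured STAT3-CKO tissue was analysed here.

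Antigen presentation genes were higher in HA IP of STAT3-CKO SCI than of WT SCI (median 1.91). More microglia or macrophage RNA would raise the markers of these cells by as much, and 16 of 17 lay below that median with their 95% interval. Thinned to equal depth, 5 of 11 tested members were called higher (median 1.88). Cells of the flow-through carrying the change into the precipitate cannot be told apart from a change in astrocytes. EdgeR called a different change between fractions for 0 of 12 members (3 higher at an unadjusted p under 0.05, 0 by DESeq2). With animal as a block, 5 were higher and 0 lower unadjusted (median 0.91), and Cd74 was called (1.76, adjusted p = 0.0155). The flow-through median was 1.28, and Cd74 was called higher there too. Genotype stays open as a biological explanation, untested apart from these.

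Other splits of the same libraries into groups of the same sizes were counted. For the 6 comparisons within a fraction and the 2 differences between fractions there were 35 splits each and the real one gave the most calls, 1 of 35, the smallest share these splits allow. Taken 1 by 1, this makes chance less likely. Without 1 library the genotype counts fell to 39 in HA IP, 2 in flow-through and 0 between fractions, and the margins of the last 2 were small. The real and highest other counts in HA IP were 3938 and 0 (WT SCI against uninjured), 171 and 49 (STAT3-CKO against WT SCI) and 1444 and 347 (STAT3-CKO SCI against uninjured). In flow-through they were 3933 and 24, 15 and 10, and 1769 and 652 in the same order, and for the differences between fractions 713 and 0 (injury) and 4 and 1 (genotype). HA IP and flow-through are paired by animal, and with the real one only 8 splits part all pairs in uninjured and in WT SCI and 4 in STAT3-CKO SCI tissue. These are too few for a share under 0.05, with real and highest other counts of 7250 and 0, 529 and 1, and 1496 and 0.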

How the results depend on the processing

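Settings that left out Rn45s, Lars2 and Mir6236 or thinned libraries to equal depth, and halved uninjured animals, were chosen only after the results were seen, and the others beforehand. Over the named genes, 3956 values kept their direction and side of the threshold, 166 no longer passed, 35 newly passed and 8 turned in sign. An alternative pseudocount was not run, since counts were used. Depth limits low genes most in WT SCI flow-through, and causes of the shifts were not tested.

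With DESeq2 the counts were 917 (171 with edgeR) for STAT3-CKO against WT SCI and 2254 (1444) for STAT3-CKO SCI against uninjured in HA IP, 213 (15) between genotypes in flow-through, 948 (529) for HA IP against flow-through in WT SCI, and 1184 (713) and 13 (4) for the differences between fractions. With only the 2 groups in the fit, which has fewer libraries for the spread, they were 36 (171), 3585 (1444), 4 (15) and, for STAT3-CKO SCI against uninjured in flow-through, 2751 (1769). Thinned, which left 9525 of 14764 genes to test in HA IP and 2903 of 12685 in flow-through, they were 948 (1444) in HA IP of STAT3-CKO SCI against uninjured, 1332 (3933) for WT injury in flow-through and 683 (1769) for STAT3-CKO SCI there. With no filter the flow-through genotype count was 131 (15), with RLE the fraction difference of genotype was 1 (4), and all 22 libraries in 1 fit gave 3369 (7250) in uninjured and 1706 (529) in WT SCI tissue. With animal as a replicate block, HA IP against flow-through gave 1096 (529) and 3105 (1496) after injury, and the differences between fractions 1934 (713) and 31 (4); in uninjured tissue the count was 9082 (7250). The block ended no call of a named gene and newly called Cx3cr1 in uninjured, Aqp4, Mbp, Syt1 and Col1a1 in WT SCI and Stat3, P2ry12, Cd3e, Mbp and Ccdc153 in STAT3-CKO SCI tissue. List tests with an estimated correlation gave 27 calls (77 with the preset one), and the shared response was 0.613 (0.64) with split controls.

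Leaving out 1 library gave 2680 to 4187 (HA IP, WT injury), 39 to 343, 848 to 1444, then in flow-through 3043 to 4003, 2 to 29 and 1244 to 1597 in the same order, 6125 to 8059, 255 to 502 and 802 to 1448 for HA IP against flow-through, and 480 to 890 and 0 to 4 for the differences between fractions. Named gene values that turned, none of them past the threshold as reported, were Aldh1l1 in HA IP of WT SCI (−0.10 and −0.02, range −0.10 to 0.42), Aqp4 (−0.24, range −0.24 to 0.33), Lcn2 (fitted at −4.14 without animal 270, where STAT3-CKO SCI had 0 counts, so no turn is shown, and at 4.48 without 154, where uninjured had 3) and Ptprz1 (0.01, 0.12 and 0.15, range −0.49 to 0.15) in HA IP of STAT3-CKO SCI against uninjured, and Col1a2 over flow-through in WT SCI (−0.47, range −0.47 to 0.75).

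The share of calls that were higher moved by over 10 points in HA IP with 2 groups (48.7% against 59.2%, 30.6% against 51.5%, 60.8% against 78.7%), thinned (40% against 51.5%) and with DESeq2 (66.5% against 78.7%). It also moved for STAT3-CKO SCI against uninjured in flow-through (74.7%; RLE 62.6%, DESeq2 54.8%, thinned 62.8%, 2 groups 57.9%), for the injury difference between fractions (56.8%; RLE 38.9%, DESeq2 41.9%, without Rn45s, Lars2 and Mir6236 45.9%) and for WT SCI fractions (65.4%; 22 libraries 77.2%, no filter 82.6%, block 50.7%). With few calls it moved for the genotypes in flow-through (73.3%; DESeq2 59.6%, no filter 55.7%, thinned 47.4%, 2 groups 0%) and their difference between fractions (25%; DESeq2 61.5%, RLE 100%). RLE moved the median log2 change of all genes from −0.09 to −0.21 for WT injury in flow-through, from 0 to −0.159 for STAT3-CKO SCI there and from 0.262 to 0.065 for the injury difference between fractions. The odds ratio of 1.488 for genes higher in HA IP was 1.898 with genes higher in both conditions and 1.462 with calls from the block. That for genes that fell (3.056) was 2.747 and 2.733. That for genes that rose (0.675) was 0.774 with the block and turned to 1.152 with genes higher in both, no longer past the threshold. With no library shared, the means over halvings were 2.163 (all), 7.365 (fell) and 0.671 (rose).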

Other observations

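The tests behind these observations were chosen beforehand, and the lists described here after the results were seen.

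Axon growth inhibitory genes in flow-through fell for 8 of 26 and rose for 3 after injury in WT (the same adjusted over the list alone; median −0.27, camera adjusted p = 0.288), while axon growth permissive genes rose for 7 of 22 and fell for 2 (8 and 2 over the list alone; median 0.82, camera adjusted p = 0.0946). In STAT3-CKO SCI against uninjured, permissive genes rose for 8 of 22 (10 with 1 lower over the list alone), a call of camera lost with an estimated correlation (adjusted p = 0.101), and inhibitory genes rose for 1 of 26 and fell for 1 (1 and 0 over the list alone). The 1 lymphocyte marker tested in flow-through rose in both injured groups (log2 5.10 in WT and 6.38 in STAT3-CKO SCI). Fibroblast and pericyte markers, which make fibrous matrix, rose for 5 of 8 in flow-through of STAT3-CKO SCI (7 over the list alone; adjusted p = 0.135 with an estimated correlation), and complement genes for 4 of 6 (4 with 1 lower over the list alone; adjusted p = 0.318).

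In HA IP of STAT3-CKO SCI against uninjured, fibroblast and pericyte markers rose for 3 of 11 (4 over the list alone, median 1.71; adjusted p = 0.0548 with an estimated correlation) and Schwann cell markers for 3 of 7 (3 over the list alone, median 2.28; adjusted p = 0.101). Neuron markers fell for 1 of 15 (1 over the list alone; median −0.72; adjusted p = 0.303) and chondroitin sulfate synthesis genes rose for 1 of 14 (4 over the list alone; adjusted p = 0.226). In HA IP over flow-through, CSPG core proteins were higher for 5 of 7 with 1 lower in uninjured, 4 of 6 in WT SCI and 5 of 7 in STAT3-CKO SCI tissue (6 with 1 lower, 4 and 6 adjusted over the list alone). Pan-reactive genes were higher for 7 of 11, 3 of 8 and 2 of 10 (7, 5 and 2 over the list alone). By the test of the difference, the injury change was higher in HA IP for 1 of 7 CSPG core proteins (1 over the list alone), and for pan-reactive genes higher for 3 of 13 and lower for 3 (4 and 4 over the list alone).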
